A study of Mus musculus with 3 samples.

How the data were processed

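RNA of single nuclei was measured in dissected liver tumour tissue of mice carrying the MUP-uPA transgene, in which a major urinary protein promoter drives urokinase-type plasminogen activator in hepatocytes and injures them. Per the labels' protocols, feeding of a Western diet began at 8 weeks of age and went on for 8 months, tumours were assessed at 10 months, and tissue pieces of 50 mg were frozen before nuclei were isolated. Libraries were made with a 10x Genomics 3′ kit, which tags each captured molecule with a unique molecular identifier (UMI). The series holds 3 libraries of 1 group, called replicates 1 to 3 here after their titles, and the labels give each library its own batch. Libraries were therefore not tested against each other. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

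The deposited counts are whole-number UMI counts per gene and barcode, not normalised, per the file headers and the values. Cell Ranger 8.0.1, genome build mm10, Seurat and Scanpy are named in the submitters' processing notes with no role or order. The annotation release, the handling of intronic reads and the use of strand in counting are not given in the sources used here. Gene identifiers were matched to the GENCODE annotation of GRCm38, the assembly that mm10 names, and 32158 of 32285 identifiers matched. Coordinates are 1-based and come from that annotation.

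Barcodes were kept with at least 500 detected genes and at most 5% of UMIs from mitochondrial genes, which removed 991 and then 1935 of the 36202 barcodes. Scrublet scores were computed per library with Scanpy 1.11.5 (Python 3.11.15). The automatic threshold of Scrublet called 1 barcode over the 3 libraries. The highest scores were removed instead, at a share of 0.8% of a library per 1000 barcodes, a rule chosen after seeing the data, and 606, 1584 and 1138 barcodes were taken out of replicates 1, 2 and 3. The analysis ran on 29948 nuclei. Counts were scaled to 10000 per nucleus and log-transformed, 3000 variable genes were chosen within library, and values were scaled and limited to 10. A neighbour graph (30 principal components, 15 neighbours) was clustered with the Leiden algorithm at resolution 1 (igraph 0.11.9, seed 1). The 4 genes of the Y chromosome used here, their partners on the X chromosome, Xist and Tsix took no part in the clustering.

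Clusters were named from 13 marker sets fixed before the data were examined. The scoring rule was set after seeing the data. A cluster took a name where at least 3 markers and a share of 0.4 of the set were 2-fold above the other nuclei and a marker stood among its 10 leading genes. Hepatocyte-like clusters were those left over with at least 3 hepatocyte markers 2-fold above the mean of the other named cell types. A marker counted if it passed either as a share of UMIs or as UMIs per nucleus. The second measure rises with depth, and hepatocyte-like nuclei were deeper than the other cell types, so a cluster could pass by depth. Clusters with markers of several types were called mixed. Clusters of low UMI count, or led by genes of another type, stayed unnamed. Cluster 23, with 806 nuclei of replicate 2 (6.90% of that library), was kept out of the hepatocyte-like class by this rule. Clusters 8 and 17, of low UMI count, held 7.95% of replicate 1 and 9.69% of replicate 3.

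Y status rested on Uty, Ddx3y, Kdm5d and Eif2s3y. A nucleus with 0 UMIs over these genes is called Y-null, which can mean loss of the chromosome, silence of the genes or a transcript that was not captured. Shares of Y-null nuclei were compared after thinning each nucleus to 2000 UMIs, with shallower nuclei left out, and the share in each class was set against 1000 sets of 4 autosomal genes matched one by one on mean thinned count in the same class and library. The excess is the observed share minus the median of the sets, over 100 minus that median. Paired differences between classes were tested with a two-sided exact sign-flip permutation test over 3 libraries, which cannot go below p = 0.25. Shares carry exact Clopper-Pearson intervals and levels exact Poisson intervals, both at 95% and both for counting error only. A count of 0 was taken to allow up to 3 counts.

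For tests across genes, counts were summed per library and class, or per library, class and Y status. They were fitted with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. Library was a block in these fits because both classes or both states came from the same library, so the pairing is by construction. The class fit held the 8 cell type classes, each with at least 20 nuclei in each library. Cycling, mixed and unnamed nuclei were left out. In the fits of Y status, Y-null and Y-detected nuclei of at least 2000 UMIs and no Xist UMI were matched 1 to 1 within library, class and decile of total UMIs, with at least 20 of each per library. T/NK cell-like nuclei gave too few at this depth and were fitted from 1000 UMIs, a choice made after seeing the data. Gene lists were tested with camera (preset correlation 0.01, and with an estimated correlation) and fry of limma 3.58.1. The 24 lists were fixed before the data were examined, and which list was taken to fit which class was chosen after. The same fits were repeated after calling nuclei null for up to 20 matched sets of autosomal genes.

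Genes named in the text followed a rule fixed beforehand. In the fits of Y status they were the 10 largest rises and 10 largest falls among genes past the threshold with 1 direction in every library, or all that passed where fewer did, or the 5 of lowest p where none passed, and the 2 members of largest change of each list fitting the class. In the class fit they were the Y genes, their X partners and Xist. Across libraries they were list members at least 4-fold apart with at least 50 counts in the highest library, at most 3 per list. Of the genes called in macrophage-like nuclei, 1 is not reported here.

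The tests were checked on simulated counts with 200 changed genes, drawn from the genes above the median level and changed alike in every library. How often changes in lower genes, or changes that differ between libraries, would be called was not measured. Nor was it measured for fits with fewer changed genes, where the Benjamini-Hochberg adjustment asks for a lower p. For Y status in hepatocyte-like nuclei (11976 genes), 98 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2 were called, with 9 false calls. For endothelial-like nuclei (5232 genes) these were 91 and 100 of 100, with 7 false calls. For T/NK cell-like against hepatocyte-like nuclei (12946 genes) they were 51 and 97 of 100, with 5 false calls. With the Y UMIs of 0%, 20% or 40% of the hepatocyte-like nuclei of replicate 1 removed, the excess at 2000 UMIs came to 1.19%, 13.7% and 26.4%, and at 4000 UMIs to −0.212%, 17.3% and 33.8%. The excess therefore lies below the share of nuclei without Y UMIs that was put in, because the sets are matched to the lowered mean.

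The alternatives were doublets kept, at least 1000 genes per nucleus, resolution 2, thinning to 1000 or 4000 UMIs, 8 Y genes in place of 4, sets matched per cluster, RLE scaling, DESeq2 1.42.0, no filter on low counts, no replicate block, matching within cluster, no depth matching, a Y-detected minimum of 2 UMIs, nuclei with Xist UMIs kept, at least 4000 UMIs, and each replicate left out in turn. Leaving replicates out of the checkpoint ligand levels and the chromosome profile was added after seeing the data.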

Results

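Single-nucleus RNA libraries were made from dissected hepatocellular carcinoma (HCC) tissue of MUP-uPA mice kept on a Western diet, a model in which injured and steatotic liver forms tumours. The series asks, by its title, about loss of the Y chromosome in cancer cells and T cells together. There were 3 libraries of 1 group. They held 8834, 14924 and 12444 barcodes and 79511976, 68300312 and 87185293 UMIs in replicates 1, 2 and 3. After filtering, 7964, 11686 and 10298 nuclei were analysed. The median nucleus held 6344 UMIs in replicate 1, 3092 in replicate 2 and 5986 in replicate 3, so a transcript at a low level was missed most often in replicate 2.

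Hepatocyte-like nuclei made up most of the tissue, at 57.8% ± 5.05 of nuclei (SD, n = 3 libraries; 17391 nuclei). Immune cells were led by macrophage-like nuclei at 8.49% ± 3.51, followed by T/NK cell-like nuclei at 2.78% ± 0.903, dendritic-like nuclei at 1.60% ± 0.486 and B cell-like nuclei at 0.708% ± 0.0181. Endothelial-like nuclei made up 6.65% ± 1.38, stellate/fibroblast-like nuclei 5.06% ± 3.09 and cholangiocyte-like nuclei 2.28% ± 0.901. Cycling nuclei, led by Diaph3, Top2a and Cenpf, made up 1.42% ± 1.13 and ranged from 0.214% (exact 95% interval 0.134 to 0.323) of replicate 3 to 2.46% (2.13 to 2.83) of replicate 1. A cluster with markers of several types held 4.84% ± 1.55, and unnamed clusters, most of them of low UMI count, 8.32% ± 1.41. Macrophage-like nuclei fell in 3 clusters, of which cluster 11, led by Gpnmb, Atp6v0d2 and Mmp12, came almost wholly from replicate 1 (387 of 405 nuclei). Of the 1709 nuclei of cluster 18, led by Adgre1 and Vsig4, 1223 came from replicate 2 and 472 from replicate 3. Cluster 7, with Lyz2, F13a1 and Ccr2 among its leading genes, held 261, 181 and 42 nuclei of replicates 1, 2 and 3. The shares of macrophage-like and cholangiocyte-like nuclei moved by over 1.5 times when the Leiden resolution was doubled, to 4.36% and 0.622%. The macrophage-like share was also lower with at least 1000 genes per nucleus (5.28%) and with doublets kept (5.16%). The order of T/NK cell-like and dendritic-like nuclei turned at both settings, to 1.59% and 2.50% and to 3.05% and 3.52%.

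**Figure D1:**
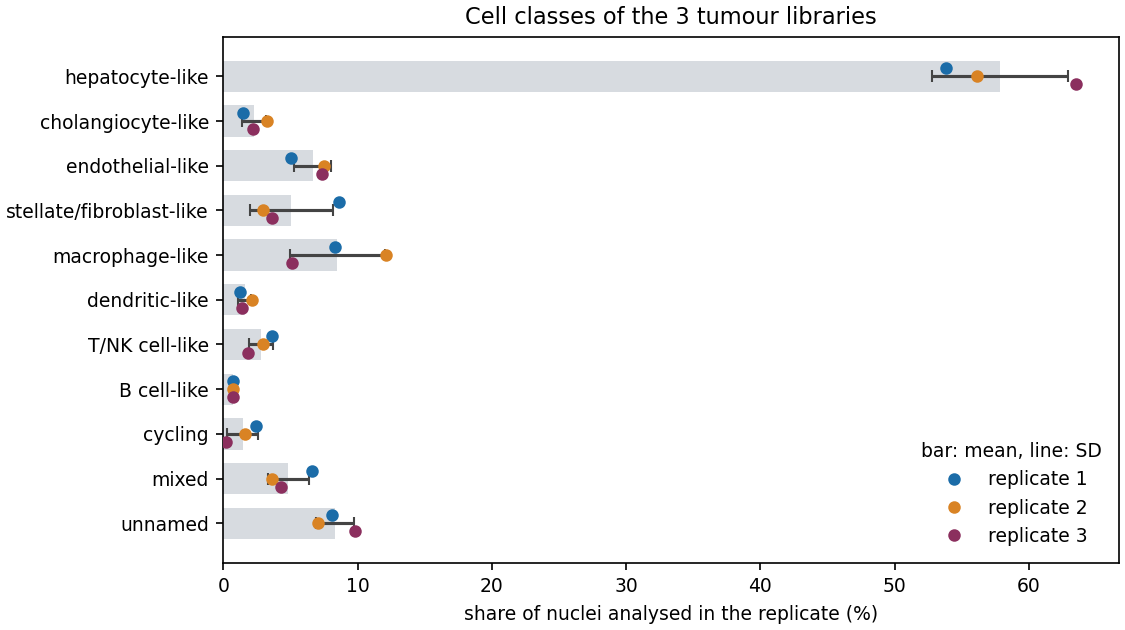
Share of nuclei (x axis, percent of the nuclei analysed in a replicate) for each cell class (y axis). Bars are the mean and lines the SD over 3 libraries, and points are the libraries. Hepatocyte-like nuclei lie between 53.9% and 63.5% in each library, and no other class exceeds 12.1%.

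Hepatocyte-like nuclei of the 3 libraries formed separate clusters with different programmes. Those of replicate 1 fell in clusters 0, 1 and 2, those of replicate 2 in clusters 14, 19, 21 and 22, and those of replicate 3 in clusters 15 (with 285 nuclei of replicate 2), 16 and 20, so the values below compare libraries and not conditions, and no test was made. Of 20 fetal and HCC genes, 13 were at least 4-fold apart between the highest and the lowest library. The oncofetal glypican Gpc3 stood at 833 CPM (UMIs scaled to the summed UMIs of the class in that library; exact 95% interval 823 to 843) in replicate 2 against 4.74 (4.17 to 5.37) in replicate 1 and 2.12 (1.76 to 2.54) in replicate 3, a range of 392-fold. The stem cell marker Prom1 followed with 51.6 CPM in replicate 2 against 0.229 and 0.526, and Bex1 with 13.2 against 0.0764 and 0.0726. Gpc3 led cluster 22, which held 2432 nuclei of replicate 2.

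Secreted proteins and bile acid genes of mature hepatocytes differed between libraries, in different orders. Among the secreted proteins, 8 of 16 genes were at least 4-fold apart, with the urinary protein Mup3 at 295 CPM in replicate 3 against 11.1 and 33.2 in replicates 1 and 2, and Mup20 at 1047 against 102 and 799. Serpina1c, an alpha-1 antitrypsin gene, stood at 31.2 CPM in replicate 1 against 239 in replicate 2 and 191 in replicate 3. In bile acid synthesis and transport, 3 of 12 genes were that far apart. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 63.6 CPM in replicate 3 against 13.5 and 19.5, the bile acid importer Slc10a1 at 109 against 15.6 and 41.5, and Cyp8b1 at 4.41 against 0.726 and 0.455. Most genes of cholesterol synthesis were lowest in replicate 3, with 6 of 12 genes at least 4-fold apart and Sqle at 3.50 CPM in replicate 3 against 38.6 and 72.7, Idi1 at 6.70 against 14.6 and 61.0, and Fdft1 at 16.8 against 50.8 and 106. Of 12 genes of fatty acid and triglyceride synthesis, 0 reached 4-fold, and Fasn lay between 67.7 and 147 CPM. Among pericentral genes 3 of 12 did, with Cyp2c37 at 13.7 CPM in replicate 3 against 1.87 and 1.65, Slc1a2 at 22.7 in replicate 2 against 73.0 and 95.8, and Oat at 7.05 in replicate 1 against 24.1 and 28.8. Among periportal genes 2 of 12 did, with the histidine-degrading enzyme Hal at 32.6, 134 and 216 CPM in replicates 1, 2 and 3 and Gls2 at 19.8, 84.9 and 64.8.

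Most of the p53, interferon and cell cycle genes that were at least 4-fold apart were highest in hepatocyte-like nuclei of replicate 2, and the endoplasmic reticulum stress genes were mixed. The antiproliferative p53 target Btg2 stood at 243 CPM there against 41.8 and 16.7, and 4 of 12 p53 targets were at least 4-fold apart, among them Tnfrsf10b (6.61, 11.3 and 1.65 in replicates 1, 2 and 3) and Bax (10.2, 47.3 and 16.7). Of 14 interferon response genes, 7 were, with Isg15 at 18.9 CPM against 1.64 and 2.70, the antiviral Rsad2 at 100.3 against 18.9 and 13.4, and Psmb8 at 12.9 against 1.15 and 6.66. Of 15 proliferation genes, 7 were, with Mki67 at 10.2 CPM against 1.36 and 1.02, Top2a at 8.04 against 2.92 and 0.889, and Cenpe at 3.15 against 1.76 and 0.399. The cycling cluster, led by the same kind of gene and largest in replicate 1, was kept out of the hepatocyte-like class, so these values cover only the nuclei left. Among genes of endoplasmic reticulum stress, 3 of the 11 measured were, with Atf3 at 18.0, 11.3 and 2.81 CPM in replicates 1, 2 and 3, Asns at 0.936, 5.37 and 1.76 and Sdf2l1 at 4.72, 16.4 and 3.87. Cluster 23, with Trib3 and Derl3 among its leading genes, was also kept out, so the replicate 2 values lack its 806 nuclei. A cluster sharing many of its leading genes was named hepatocyte-like at resolution 2. Cluster 2 of replicate 1, with Dnajc3 and Sel1l among its leading genes, stayed in. Genes of other cell types were also highest in replicate 2, which bears on each of these groups. Of 6 major histocompatibility complex (MHC) class II genes, 4 were at least 4-fold apart, with H2-Ab1 at 35.6 CPM in replicate 2 against 2.46 and 9.84, and H2-Aa and H2-Eb1 were likewise highest there, at 72.4 and 51.9. Of 10 lipid-associated macrophage genes 7 were, with Fabp5 at 86.1 against 1.82 and 5.35, Gpnmb at 23.8 against 6.02 and 0.835 and Trem2 at 3.30 against 0.191 and 0.272.

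The remaining lists were measured in hepatocyte-like nuclei as markers of other cells. Of 10 Kupffer genes 5 were at least 4-fold apart, with Clec4f at 0.306, 4.18 and 2.63 CPM in replicates 1, 2 and 3, Id3 at 6.06, 37.7 and 5.48 and Folr2 at 0.344, 2.02 and 1.02. Of 12 fibrosis genes 4 were, all highest in replicate 2 among those named: Acta2 at 2.53 CPM, Thbs1 at 3.92 and Col1a1 at 8.75. Tox, a transcription factor of exhausted T cells that hepatocyte-like nuclei also held, stood at 701 CPM in replicate 1 against 159 and 121, and Tox2 at 35.8 in replicate 2 against 6.80 and 1.74. Among effector genes, 3 of 12 were, with Ccl5 at 19.9 in replicate 2 against 0.611 and 1.65, Nkg7 at 1.42 against 0.0955 and 0.290 and Ccl4 at 1.51 against 0.669 and 0.345. Ikzf2 stood at 36.4 CPM in replicate 3 against 3.97 and 1.79, and Tnfrsf18 at 1.68 in replicate 2 with 2 counts in replicate 1. Of 9 naive and memory genes and of 12 checkpoint ligands, 1 each was, Klf2 (5.66 in replicate 2 against 1.39 and 1.31) and Cd80 (0.544 in replicate 3 against 1.85 and 2.84).

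Checkpoint ligands, the surface and secreted proteins that restrain T cells, were spread over immune and epithelial classes. Cd274, which encodes PD-L1, stood at 102.7 ± 62.5 CPM in macrophage-like nuclei (mean and SD, n = 3 libraries) and 49.0 ± 10.7 in dendritic-like nuclei against 6.76 ± 0.939 in hepatocyte-like nuclei. The costimulatory ligand Cd86 was at 253 ± 49.7 in macrophage-like and 174 ± 52.5 in dendritic-like nuclei, and Cd80 at 58.0 ± 10.6 and 58.2 ± 13.8. Vsir was at 88.7 ± 29.6 in macrophage-like and 47.6 ± 14.3 in endothelial-like nuclei. Epithelial classes held Nectin2, highest in cholangiocyte-like nuclei at 106.9 ± 1.81, and the LAG-3 ligand Fgl1 and galectin 9 gene Lgals9, highest in hepatocyte-like nuclei at 120.4 ± 46.2 and 199 ± 54.6. Classes were clustered on the same nuclei, so these levels were not tested.

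UMIs of Y genes were counted in nuclei of every class, with no background of free RNA taken off, at 6.99 ± 2.63 UMIs per 10000 in hepatocyte-like nuclei (9.86, 6.40 and 4.71 in replicates 1, 2 and 3), 6.17 ± 1.72 in T/NK cell-like, 6.42 ± 0.711 in macrophage-like and 4.49 ± 0.837 in stellate/fibroblast-like nuclei. The 4 genes lie in the first 1.3 megabases of the Y chromosome of GRCm38 (mm10). Uty, a histone demethylase-related gene (ENSMUSG00000068457, Y, 1096861 to 1245759, minus strand), gave 41613, 20593 and 21868 UMIs in replicates 1, 2 and 3, and Ddx3y, an RNA helicase (ENSMUSG00000069045, 1260771 to 1286629, minus strand), gave 10667, 9314 and 7219. The histone demethylase Kdm5d (ENSMUSG00000056673, 897788 to 956786, plus strand) gave 8481, 4942 and 5370, and the translation initiation gene Eif2s3y (ENSMUSG00000069049, 1010543 to 1028847, plus strand) gave 11626, 7460 and 6765. Each has a partner of similar sequence on the X chromosome (Kdm6a, Ddx3x, Kdm5c and Eif2s3x), so some reads could have been counted for the partner.

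Over all libraries, Y genes were lower in the other classes than in hepatocyte-like nuclei, but not in every library. In replicates 1 and 2, each fitted class held fewer Y UMIs per 10000 than hepatocyte-like nuclei. In replicate 3, hepatocyte-like nuclei held 4.71, against 5.96 in macrophage-like, 5.22 in T/NK cell-like and 5.03 in dendritic-like nuclei. The rest were lower there, at 4.65 in B cell-like, 4.62 in endothelial-like, 4.15 in stellate/fibroblast-like and 3.89 in cholangiocyte-like nuclei. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over 12950 genes, 24 of 28 pairs of gene and class were called lower and 0 higher, namely all 4 genes in cholangiocyte-like, endothelial-like, stellate/fibroblast-like and B cell-like nuclei, 3 in dendritic-like and T/NK cell-like nuclei and 2 in macrophage-like nuclei. Kdm5d fell in all 7 classes, from −0.54 ± 0.18 on the log2 scale (SE) in macrophage-like to −0.78 ± 0.24 in B cell-like nuclei. Uty was at −0.60 ± 0.17 in T/NK cell-like nuclei (adjusted p = 0.00787, edgeR), and in macrophage-like nuclei it was at −0.31 ± 0.17 and did not pass (adjusted p = 0.128, edgeR). Ddx3y did not pass in macrophage-like, dendritic-like or T/NK cell-like nuclei, at −0.12, −0.37 and −0.32. Of the X partners, Kdm5c fell in all 7 classes, between −0.45 and −0.84, and Kdm6a in 4, while Ddx3x and Eif2s3x were called in 0 by this test. With RLE, with DESeq2 and without the filter on low counts, Kdm5c was called in 2 classes and Kdm6a in 1, and Kdm5c was called in 0 without replicate 1 or replicate 2. DESeq2 called Ddx3x and Eif2s3x higher in 2 classes each. Xist was too low to be tested.

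The size of these falls rests on the scaling. With TMM the median of all genes lay below 0 in every class, from −0.13 in cholangiocyte-like to −0.45 in B cell-like nuclei, and with RLE it lay 0.24 to 0.35 higher. Relative to the median of all genes, the median Y gene lay at −0.52 in cholangiocyte-like, −0.42 in endothelial-like, −0.43 in stellate/fibroblast-like, −0.24 in macrophage-like, −0.46 in dendritic-like, −0.32 in T/NK cell-like and −0.30 in B cell-like nuclei. With RLE these were −0.51, −0.41, −0.43, −0.23, −0.45, −0.32 and −0.29. The number of pairs called lower dropped from 24 to 4 with RLE, with DESeq2 and without the filter on low counts, to 0 without the replicate block and without replicate 2, and to 1 without replicate 1. It was 19 without replicate 3. With each class fitted alone against hepatocyte-like nuclei, 1 Y gene was called in either direction in cholangiocyte-like, 1 in endothelial-like, 2 in stellate/fibroblast-like and 3 in dendritic-like nuclei, and 0 in macrophage-like, T/NK cell-like and B cell-like nuclei. Ddx3y in macrophage-like and Kdm6a in dendritic-like nuclei turned positive with RLE and DESeq2 (0.14 and 0.21 with each). Alb, the albumin gene, was also counted outside hepatocyte-like nuclei. It stood at 4623 ± 2569 CPM in hepatocyte-like nuclei, 4121 ± 2597 in T/NK cell-like, 3449 ± 2505 in B cell-like and 2752 ± 1657 in endothelial-like nuclei. Free hepatocyte RNA is a possible source, and no background was estimated.

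**Figure D2:**
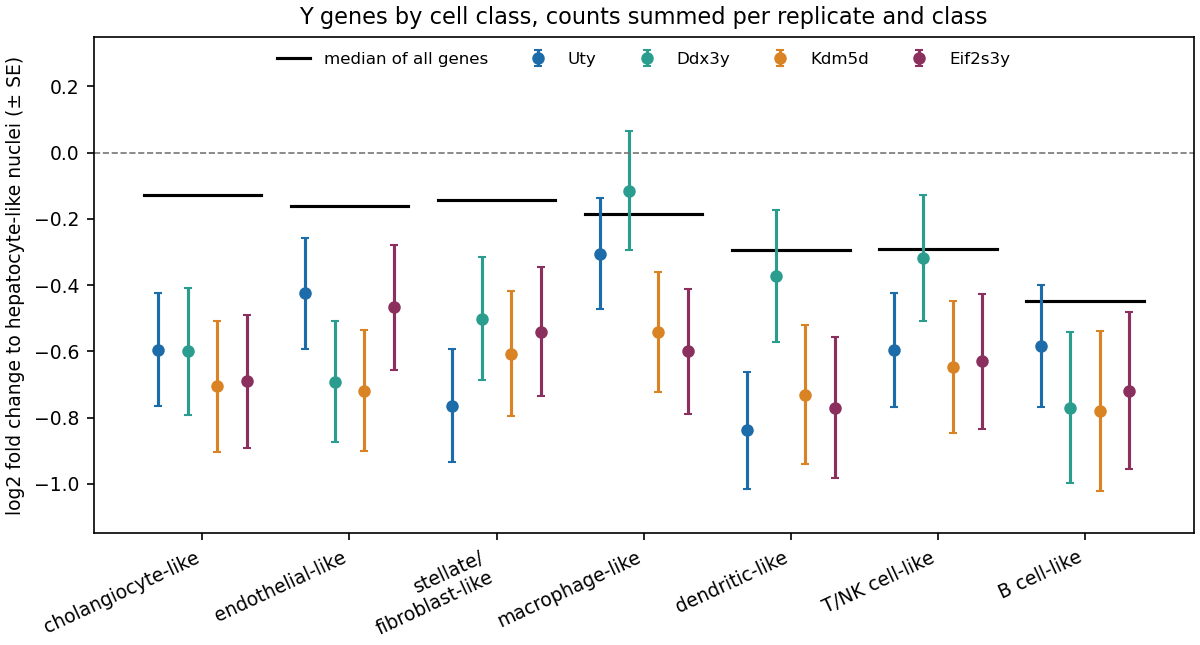
Log2 fold change (y axis) of the 4 Y genes in each class against hepatocyte-like nuclei of the same libraries, from edgeR with the library as block; error bars are the SE. The estimates lie below 0 in this fit with TMM, and Ddx3y in macrophage-like nuclei, at −0.12, turned to 0.14 with RLE.

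Nuclei with 0 UMIs of the 4 Y genes were frequent in every class at equal depth. Thinned to 2000 UMIs, Y-null nuclei made up 17.9% (exact 95% interval 16.8 to 19.1) of hepatocyte-like nuclei in replicate 1, 31.2% (29.9 to 32.4) in replicate 2 and 50.0% (48.8 to 51.3) in replicate 3. Before thinning the shares were 1.68%, 20.7% and 30.1%. At a mean of 33.1% in hepatocyte-like nuclei, the paired difference was 7.17 ± 2.39 percentage points in cholangiocyte-like nuclei (SD, n = 3), higher in 3 of 3 libraries, with p = 0.25 in the exact sign-flip test, the smallest that 3 pairs can give. Endothelial-like nuclei differed by 8.37 ± 14.7 points and stellate/fibroblast-like nuclei by 12.2 ± 12.6, each higher in 2 of 3 libraries (exact p = 0.5). In replicates 1, 2 and 3 these were 23.3, 7.82 and −6.01 points in endothelial-like and 19.1, 19.9 and −2.32 in stellate/fibroblast-like nuclei. The endothelial-like mean was 0.905 without replicate 1 and 15.6 without replicate 3, and the stellate/fibroblast-like mean was 19.5 without replicate 3 and 6.86 thinned to 4000 UMIs. Dendritic-like nuclei differed by 6.77 ± 14.4 points (2 of 3, exact p = 0.5; 17.5, 12.4 and −9.59 in replicates 1, 2 and 3), cycling nuclei by 6.66 ± 9.96 (3 of 3, exact p = 0.25; 0.912 without replicate 3, which held 22 such nuclei) and macrophage-like nuclei by −4.08 ± 12.0 (1 of 3 higher, exact p = 0.75). Macrophage-like nuclei lay at 2.17 points without replicate 3. Thinned to 4000 UMIs, endothelial-like nuclei lay at −1.19 points, cycling nuclei at 2.75 and macrophage-like nuclei at −8.23 (−0.413, −2.59 and −21.7 in replicates 1, 2 and 3). In B cell-like nuclei, replicate 2 held under 20 nuclei of this depth, and the shares were 19.05% and 38.7% in replicates 1 and 3 (21 and 31 nuclei).

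T/NK cell-like nuclei of the same libraries bear on the question of concurrent loss. Their Y-null share at 2000 UMIs was 21.7% (13.8 to 31.6; 92 nuclei) in replicate 1, 48.3% (29.4 to 67.5; 29 nuclei) in replicate 2 and 46.8% (34.0 to 59.9; 62 nuclei) in replicate 3, against 17.9%, 31.2% and 50.0% in hepatocyte-like nuclei. The paired difference was 5.88 ± 10.3 points, higher in 2 of 3 libraries (exact p = 0.5). It was 3.80, 17.1 and −3.26 points in replicates 1, 2 and 3, and the mean was 0.267 without replicate 2, 10.5 without replicate 3, 2.90 thinned to 1000 UMIs and −0.170 with doublets kept. The thinning left out 195, 314 and 125 of the T/NK cell-like nuclei, and before thinning the shares were 32.4%, 54.8% and 41.7%. Set against matched autosomal gene sets, the excess of Y-null T/NK cell-like nuclei was 0%, 11.8% and 2.94% in replicates 1, 2 and 3, at percentiles 49.8, 88.7 and 62.2 of the sets. No excess stood out from the sets. With 92, 29 and 62 nuclei, and no background of free RNA taken off, the comparison cannot exclude loss in part of these nuclei. No test of a relation between the shares in both classes was made over 3 libraries.

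Hepatocyte-like nuclei of replicate 3 lacked Y UMIs more often than genes of the same level lacked theirs. Their Y-null share of 50.0% stood above all 1000 matched sets, whose median was 40.1%, an excess of 16.6%, and the excess was 23.2% at 4000 UMIs. In replicates 1 and 2 the excess was 0.459% and 1.99%, at percentiles 59.6 and 82.9. With sets matched per cluster, replicate 2 had an excess of 3.25% at percentile 95.4, and its cluster 22 had 6.89% at 4000 UMIs (percentile 99.5). X partners, measured the same way, were absent from 30.7%, 43.2% and 37.1% of hepatocyte-like nuclei in replicates 1, 2 and 3. In replicate 3 the share of Y-null nuclei was 40.3% at 2000 to 4000 UMIs, 30.7% at 4000 to 8000, 27.8% at 8000 to 16000 and 19.05% (14.99 to 23.7; 64 of 336 nuclei) above that, where a Poisson count of the same mean gives 0.0294% and X partners were absent from 0.595%. At 8000 to 16000 UMIs, 3.38% (2.40 to 4.61) of replicate 2 were Y-null against a Poisson share of 0.155%, and 0.239% (0.0651 to 0.610) of replicate 1 against 0.00750%. In the deepest nuclei of replicates 1 and 2, 0 of 1077 and 0 of 149 were Y-null, which allows up to 0.342% and 2.45% (upper limits of the exact intervals). Cholangiocyte-like nuclei of replicate 3 had an excess of 11.2% (179 nuclei, percentile 98.7) against −1.75% and 6.80% in replicates 1 and 2 (percentiles 25.1 and 92.3). Endothelial-like nuclei had 9.03%, 5.19% and 4.42% in replicates 1, 2 and 3, all inside the central range of the sets (percentiles 97.0, 88.8 and 84.4), and cycling nuclei of replicate 3 an excess of 41.7% over 22 nuclei. Unnamed nuclei of replicate 3, nearly all of cluster 17 and of low UMI count, had an excess of 21.1% (129 nuclei, percentile 100), which is above that of the hepatocyte-like nuclei. Hepatocyte markers in those cholangiocyte-like nuclei stood at 62.6 UMIs per 10000 in Y-null and 57.2 in Y-detected nuclei.

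**Figure D3:**
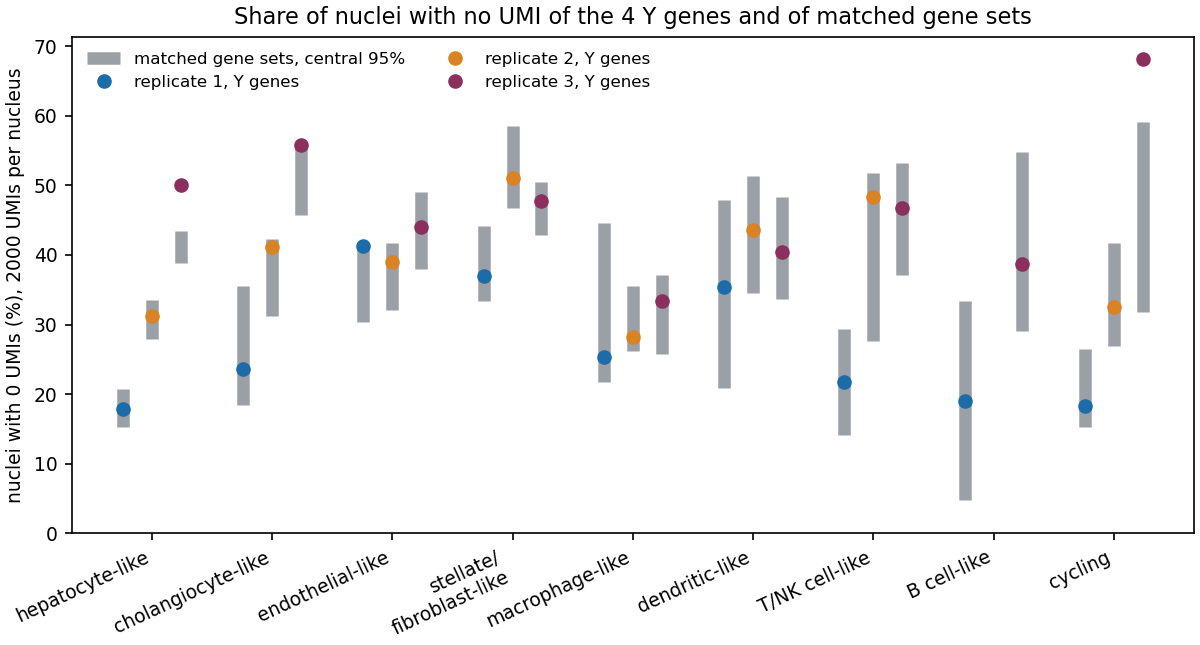
Share of Y-null nuclei (y axis, percent) at 2000 UMIs per nucleus by class (x axis) and replicate (points). Grey bars are the central range of 1000 matched sets of 4 autosomal genes, whose median is not drawn. In hepatocyte-like nuclei of replicate 3 the share was 50.0% against a set median of 40.1%.

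**Figure D4:**
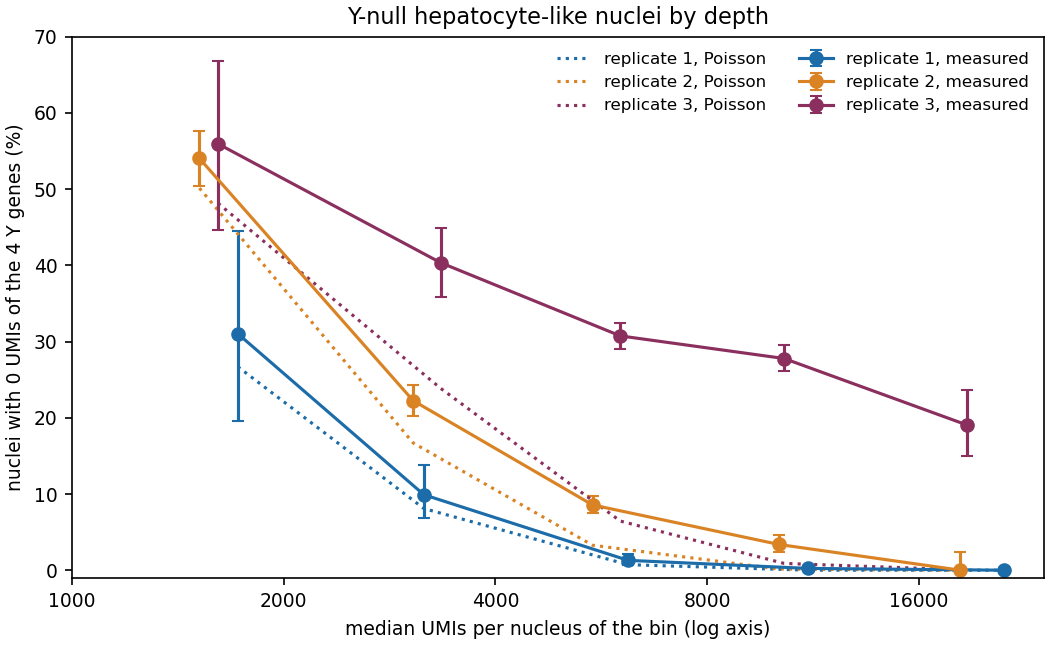
Share of Y-null hepatocyte-like nuclei (y axis, percent, exact 95% intervals) against the median UMIs per nucleus of the depth bin (x axis, log scale) for each replicate; dotted lines are the Poisson share at the same mean. Replicate 3 is at 27.8% from 8000 UMIs and lower, at 19.05%, in the deepest bin, where replicates 1 and 2 are at 0.

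Between Y-null and Y-detected hepatocyte-like nuclei of matched depth (50, 614 and 1894 pairs in replicates 1, 2 and 3), most pericentral genes had negative and most fetal genes positive log2 changes, and no gene passed. The quasi-likelihood test of edgeR called 0 of 11976 genes after Benjamini-Hochberg adjustment, with 195 at an unadjusted p under 0.05, and DESeq2 called 0, with 24 under 0.05. The lowest p belonged to Cyp2c29, a pericentral cytochrome P450, at −1.09 ± 0.15 on the log2 scale (SE; adjusted p = 0.0869, edgeR; lower in 3 of 3 libraries). The next 4, which did not pass either, were Ntrk2 (−1.55), 4930422I22Rik (1.15), Rsad2 (−0.99) and Ifi213 (1.72). Matching within cluster called 19 genes, 13 higher and 6 lower, and no depth matching called 38.

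Of the pericentral list, 12 of 12 genes had a negative log2 change with a median of −0.58, led by Cyp2c37 (−1.29 ± 0.28) and Cyp2c29, and 0 fell over all genes and 3 when adjusted over the list alone. Y-null nuclei were spread unevenly over clusters: in replicate 3 they made up 17.3% of cluster 15, which is led by pericentral genes, and 33.1% of clusters 16 and 20 each. Matched on depth within cluster, Cyp2c29 was at −0.21 ± 0.12 and Cyp2c37 at −0.59 ± 0.29. Camera with a preset correlation called the list lower (adjusted p = 9.97e-06), which was lost with an estimated correlation (adjusted p = 0.678), and fry gave an adjusted p of 0.764. Fetal and HCC genes had a median of 0.21 with 11 of 14 positive, led by H19 (1.36 ± 0.48) and Spink1 (0.56 ± 0.20), an adjusted p of 7.25e-04 with camera and of 0.678 with an estimated correlation. Secreted proteins (median 0.12, camera adjusted p = 0.0105), cholesterol synthesis (0.08, 0.0439) and bile acid genes (−0.15, 0.0142) were called with the preset correlation and each lost with an estimated correlation, at an adjusted p of 0.678. Their largest changes were Alb (0.27 ± 0.11) and Hpx (0.24 ± 0.14), Sqle (0.38 ± 0.17) and Cyp51 (0.28 ± 0.14), and Cyp8b1 (−1.04 ± 0.39) and Cyp7a1 (−0.90 ± 0.35). The other 16 of the 21 lists were not called, and over all lists 0 genes rose and 5 fell when adjusted over the list alone. Cyp7a1 was at 1.09 without replicate 3. Values of their leading members were Hal 0.16 and Sdsl 0.20 (periportal), Scd1 0.23 and Dgat2 −0.17 (lipid synthesis), Tpx2 1.18 and Cenpf 0.87 (proliferation), Eda2r 0.34 and Gdf15 −0.32 (p53 targets), Asns 0.40 and Atf3 0.30 (endoplasmic reticulum stress), Rsad2 −0.99 and Ifit3 −0.78 (interferon response) and Cd274 −0.23 and Cd86 0.12 (checkpoint ligands). The X partners lay between −0.08 and 0.10 with SE from 0.11 to 0.15.

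Genes of the other chromosomes, grouped by chromosome, had medians near 0 between Y-null and Y-detected hepatocyte-like nuclei. Against a median of 0.00 over all genes, the lowest median log2 change belonged to chromosome 12 (−0.10 over 430 genes, −0.11 to −0.05 with a replicate left out) and the highest to chromosome 15 (0.07 over 467 genes, 0.01 to 0.16), and chromosome X lay at −0.01 over 332 genes. No test was made across genes.

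In endothelial-like nuclei, Mecom, a transcription factor of vascular endothelium, rose by 0.69 ± 0.13 on the log2 scale in Y-null nuclei, and Sntg1, a syntrophin gene that also leads the stellate/fibroblast-like cluster, fell by 1.59 ± 0.29 (SE; both adjusted p = 0.0198, edgeR, 1 direction in 3 of 3 libraries, 5232 genes tested, 306 at an unadjusted p under 0.05). At resolution 2, 408 nuclei led by Mecom (30, 162 and 216 in replicates 1, 2 and 3) formed a cluster apart from the endothelial-like ones. The class was not split at resolution 1, so the fit did not match on such subgroups. In macrophage-like nuclei 2 genes were called, of which the growth factor gene Igf1 fell by 0.88 ± 0.18 (adjusted p = 0.0182, edgeR, in 3 of 3 libraries; 3611 genes tested, 256 at an unadjusted p under 0.05). The macrophage-like class joined 3 clusters, and this fit did not match on them. Matched on depth within cluster, edgeR called 3 macrophage-like genes, 2 higher and 1 lower. In cholangiocyte-like nuclei, fitted in replicates 2 and 3 alone, the NF-κB inhibitor gene Nfkbia fell by 2.14 ± 0.48 (adjusted p = 0.0387) and the receptor gene Igf1r fell by 1.34 ± 0.31 (adjusted p = 0.0438), both in 2 of 2 libraries by edgeR. DESeq2 called 0 genes in each of these classes, with 28, 11 and 2 at an unadjusted p under 0.05, and edgeR called 0 without the replicate block. Without replicate 3 the endothelial-like count was 0 and without replicate 1 it was 9, and in macrophage-like nuclei it was 0 without replicate 1 and 5 without replicate 3.

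With the preset correlation, camera called 4 of 20 lists in macrophage-like, 2 of 21 in endothelial-like and 1 of 18 in cholangiocyte-like nuclei, all lost with an estimated correlation (lowest adjusted p = 0.829, 0.745 and 0.945). Over all lists, 6, 3 and 1 genes rose and 5, 5 and 4 fell when adjusted over the list alone, against 0 list members over all genes. In macrophage-like nuclei, lipid-associated macrophage genes had a median of −0.27 with 2 of 8 positive, led by Spp1 (−0.97 ± 0.26) and Gpnmb (−0.74 ± 0.22), and 0 fell over all genes and 2 when adjusted over the list alone; camera gave an adjusted p of 0.0141 and, with an estimated correlation, an adjusted p of 0.829. Kupffer genes (Vsig4 −0.56, Nr1h3 −0.29) and MHC class II genes (H2-Ab1 0.30, Cd74 0.15) were not called. Secreted hepatocyte proteins, read here as a measure of free RNA, differed in sign between classes. Their median was −0.15 in endothelial-like nuclei (camera adjusted p = 9.83e-05, and 0.745 as adjusted p with an estimated correlation) and 0.18 in macrophage-like nuclei (0.0134, and 0.829 as adjusted p with an estimated correlation). In endothelial-like nuclei, the interferon genes Rsad2 (0.96) and Stat2 (−0.23) did not pass, nor did Spink1 (0.99) and Lcn2 (0.82) among the fetal and HCC genes in cholangiocyte-like nuclei.

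In stellate/fibroblast-like nuclei the edgeR test called 0 of 5222 genes, with 234 at an unadjusted p under 0.05, and DESeq2 called 0, with 13. The lowest p values belonged to Rbfox1 (1.06), Col8a1 (−0.77), Ncam1 (−1.06), Ctnna3 (−2.23) and Pcdh9 (−0.51), and among fibrosis genes Acta2 (0.38) and Col1a1 (0.31) were largest and not called. In dendritic-like nuclei, with replicates 2 and 3 alone, edgeR called 0 of 1440 genes, with 89 under 0.05, and DESeq2 called 0, with 2; Zc3h12c (−1.56), Cd83 (1.75), Ptma (1.15), Fhit (−1.42) and Acap2 (1.22) had the lowest p, and H2-Ab1 (0.27) and Ciita (−0.27) led the MHC class II list. In T/NK cell-like nuclei of at least 1000 UMIs, edgeR called 0 of 2988 genes, with 103 at an unadjusted p under 0.05, and DESeq2 called 0. The 5 of lowest p were Slco1b2 (−1.14), Dpyd (−0.69), Rybp (−1.26), Trappc9 (−0.87) and Sult2a8 (−1.44), of which Slco1b2 and Sult2a8 are hepatocyte genes. The exhaustion genes Tox (0.37 ± 0.18) and Entpd1 (0.25), the regulatory genes Ikzf2 (−0.31) and Nrp1 (0.00), the effector genes Tbx21 (−0.64) and Ccl5 (−0.42) and the naive and memory genes Klf2 (1.12 ± 0.43) and Lef1 (−0.34) did not pass, and none of these 4 lists was called. Bile acid genes had a median of −0.36 there (camera adjusted p = 0.0209, and 0.703 as adjusted p with an estimated correlation). X partners passed in 0 of these 6 classes by edgeR.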

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

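The tests for nuclei of a female animal and on the ratio of Tsix to Xist in replicates 1 and 3 were chosen after the result was seen. Xist, the RNA that coats the silent X chromosome of female cells, and Tsix, its antisense gene, were not compared between groups, though nuclei with an Xist UMI were left out of the fits of Y status. With no control samples each count was held against the limit that a count of 0 allows. Over all barcodes of replicates 1, 2 and 3 there were 44, 247 and 39 UMIs of Xist and 16, 717 and 8 of Tsix. Of those in replicate 2, 103 UMIs of Xist and 294 of Tsix lay in the 1701 nuclei of hepatocyte-like cluster 21, a ratio of 2.85 (exact 95% interval 2.27 to 3.61) against 1.67 (1.36 to 2.05) in all other nuclei.

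Nuclei of a female animal in the sample would lack Y transcripts, and the tables argue against them. The 316 nuclei of cluster 21 with Xist or Tsix held 6.64 Y UMIs per 10000 against 6.75 in the others, with a lower bound of 93.7% of their level. Xist read on the wrong strand as Tsix is argued against by the ratio in all barcodes of replicates 1 and 3, 0.289 (0.176 to 0.460), only if counting on the wrong strand affects each library alike. That premise was not tested, and each library was its own batch. The bound set before the data were examined, a ratio 2 times that of the other nuclei, was not met by cluster 21 (1.71 times), because the remaining nuclei of replicate 2 had a high ratio too (3.04 outside the cluster). Transcription of the X-inactivation centre in male hepatocyte-like nuclei may remain as a hypothesis, the design names no group to test it, and the use of strand in counting is not given in the sources used here.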

How the results depend on the processing

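Leaving replicates out of the chromosome profile and the checkpoint ligand levels, and the fit of T/NK cell-like nuclei from 1000 UMIs, were chosen after the result was seen. Over 176 results and 1259 alternative values, 875 were the same, 232 weaker, 16 stronger, 43 reversed and 93 moved. The cause was not tested except where named. The same means 1 direction and side of the threshold for tested values, and within 1.5 times for counts. For shares, excesses and levels it means within their SD, SE or interval. Many of these values belong to named genes that were not called, where 29 of 584 values reversed and 16 became called. Of the 6 genes called by Y status, 24 of 60 alternative values kept the call. With DESeq2, Cd274, Cd86 and Cyp7a1 in hepatocyte-like nuclei were at 0.00865, −0.0537 and 0.0454, Ddx3y in macrophage-like and Kdm6a in dendritic-like nuclei at 0.14 and 0.21 against hepatocyte-like nuclei, Y genes called lower numbered 4 in place of 24, and 0, 0 and 0 genes were called by Y status in cholangiocyte-like, endothelial-like and macrophage-like nuclei. RLE normalization gave 0.14, 0.21 and 4 for the same Ddx3y, Kdm6a and Y gene results. No filter on low counts gave 0.0213 for Ddx3y in macrophage-like nuclei, 4 Y genes, and 1, 9, 3 and 0 genes by Y status in cholangiocyte-like, endothelial-like, hepatocyte-like and macrophage-like nuclei, in place of 2, 2, 0 and 2. No replicate block gave 0.0603 for Cd274 and −0.20 for Cd86 in hepatocyte-like nuclei, 0 Y genes and 0, 0 and 0 genes in cholangiocyte-like, endothelial-like and macrophage-like nuclei, and the X partner Kdm5c was called in 0 classes in place of 7. With Y-detected at 2 or more UMIs, Atf3 was at −0.34 in hepatocyte-like and Spp1 at 0.20 in macrophage-like nuclei, where 11 genes were called. With nuclei with Xist UMIs kept, Atf3, Eda2r and Ifit3 in hepatocyte-like nuclei were at −0.10, −9.39e-05 and 0.0261, and 0 genes were called in cholangiocyte-like and 0 in macrophage-like nuclei. At least 4000 UMIs gave −0.00569 for Atf3, 0.15 for Kdm6a and 1 gene called in hepatocyte-like nuclei. Matched on depth within cluster, Atf3, Cenpf, Hal, Ifit3 and Kdm6a in hepatocyte-like nuclei were at −0.18, −0.12, −0.00492, 0.0921 and 0.0120, Nr1h3 in macrophage-like nuclei at 0.0186, and 19 genes were called in hepatocyte-like nuclei. No depth matching gave −0.31 for Atf3, 0.11 for Ciita in dendritic-like and 0.0824 for Nr1h3 in macrophage-like nuclei, and 5, 3, 398, 38 and 83 genes in cholangiocyte-like, dendritic-like, endothelial-like, hepatocyte-like and macrophage-like nuclei, from fits that also held more nuclei. Shares of nuclei moved with at least 1000 genes per nucleus (B cell-like 0.432%, T/NK cell-like 1.59%, dendritic-like 2.50%, hepatocyte-like 67.5%, macrophage-like 5.28%, mixed 7.40%, unnamed 0%), with resolution 2 (cholangiocyte-like 0.622%, dendritic-like 2.43%, endothelial-like 5.13%, macrophage-like 4.36%, mixed 10.7%) and with doublets kept (dendritic-like 3.52%, macrophage-like 5.16%, mixed 8.75%, unnamed 5.77%), where the T/NK cell-like minus hepatocyte-like Y-null difference was −0.170 points. Thinned to 1000 UMIs the macrophage-like difference was 0.3303 points, and thinned to 4000 UMIs the endothelial-like difference was −1.19 and the mean excess 15.6% in cholangiocyte-like, 3.34% in endothelial-like and 4.60% in stellate/fibroblast-like nuclei and 23.2% in hepatocyte-like nuclei of replicate 3. With 1 replicate left out in turn, lowest and highest values in hepatocyte-like nuclei were −0.0433 to 0.23 for Cd86, −0.17 to 0.00789 for Kdm6a, −0.10 to 0.69 for Atf3, −1.29 to 1.09 for Cyp7a1, −0.0113 to 0.54 for Hpx, −0.11 to −0.0528 for chromosome 12 and 0.0102 to 0.16 for chromosome 15. They were −0.54 to 0.18 for Nr1h3 and −0.0230 to 0.25 for Cd74 in macrophage-like and −0.0171 to 0.59 for Col1a1 in stellate/fibroblast-like nuclei, −9.805 to 2.17 points for the Y-null share of macrophage-like minus hepatocyte-like nuclei, and 0 to 9 and 0 to 5 genes called in endothelial-like and macrophage-like nuclei. Against hepatocyte-like nuclei, they were −0.0923 to 0.11 for Kdm6a in dendritic-like, −0.51 to 0.0588 for Ddx3y in T/NK cell-like and −0.30 to 0.21 for Ddx3y in macrophage-like nuclei, and 0 to 19 Y genes. Not run were at least 4000 UMIs in the other classes and T/NK cell-like nuclei by Y status at 2000 UMIs. The alternatives other than DESeq2 were not run for the T/NK cell-like fit from 1000 UMIs. No replicate was left out of the fits of cholangiocyte-like and dendritic-like nuclei, which held 2 libraries. Pairs of B cell-like nuclei thinned to 2000 or 4000 UMIs were not run, nor Y-detected at 2 or more UMIs in dendritic-like nuclei. Thinned to 1000 UMIs, the B cell-like minus hepatocyte-like Y-null difference was 5.38 ± 10.0 points, higher in 2 of 3 libraries (exact sign-flip test, p = 0.5). Depth limits Y status in T/NK cell-like and B cell-like nuclei, whose medians were 1533, 1069 and 1592 and 1642.5, 1055 and 1710 UMIs, and B cell-like nuclei were not fitted by Y status.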

Other observations

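In this part, the test of a mixture of clusters and the splits of the sums were chosen after the result was seen. Summed over the T/NK cell-like class, with no background of free RNA taken off, transcripts of several T cell states were counted. Tox, a transcription factor of exhausted T cells, stood at 1014 ± 272 CPM (mean and SD, n = 3 libraries) and the ectonucleotidase gene Entpd1 at 93.8 ± 16.9, while the inhibitory receptor genes Pdcd1 (14.5 ± 6.38), Lag3 (7.05) and Tigit (6.15) were near the floor, Pdcd1 with 11, 10 and 4 UMIs in replicates 1, 2 and 3. Among the 9 genes of naive and memory cells, Ccr7 was lowest at 9.22 ± 6.14 CPM and the 4 highest were Bach2 at 473 ± 76.6, Il7r at 271 ± 96.4, Satb1 at 234 ± 75.6 and Lef1 at 166 ± 29.2. The chemokine gene Ccl5 of effector cells ranged from 76.4 CPM in replicate 1 to 845 in replicate 2 and 261 in replicate 3, beside Nkg7 at 109 ± 115, Tbx21 at 113 ± 16.8 and Gzma at 51.6 ± 41.6. Ikzf2 stood at 440.2 ± 82.0 and Nrp1 at 325 ± 54.6, with Foxp3, the defining gene of regulatory T cells, at 2, 2 and 9 UMIs.

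Macrophage-like nuclei of replicate 1 held most transcript of Gpnmb, a gene of lipid-associated macrophages, at 751 CPM against 101 and 68.3 in replicates 2 and 3. Mmp12 stood at 218 ± 125 CPM, the lipase gene Lpl at 243 ± 39.3 and Trem2 at 30.7 ± 25.6. The Kupffer cell gene Clec4f had the other order, at 47.5, 165 and 266 CPM, beside Cd5l at 579.9 ± 138, Vsig4 at 240.4 ± 88.4 and Timd4 at 20.3 ± 2.51. In stellate/fibroblast-like nuclei the fibrillar collagen gene Col3a1 was highest in replicate 2, at 2684 CPM against 638 and 1161, with Col1a1 at 503 ± 387, the fibronectin gene Fn1 at 827 ± 393, Col5a2 at 806 ± 232 and Acta2, a gene of activated stellate cells, at 159 ± 156.

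Y-null hepatocyte-like nuclei of replicate 3 exceeded matched autosomal sets, and 3 technical explanations are argued against. Low depth per nucleus would bring the share in nuclei of at least 16000 UMIs to its Poisson value, and it was 19.05%, 648 times that value. The multiple alone does not set replicate 3 apart, since at 8000 to 16000 UMIs it was 31.8 in replicate 1 and 31.1 in replicate 3. The shares at that depth were 0.239% and 27.8%. Uneven expression not shared by the 4 genes would leave the other 3 genes as often absent with as without Uty, and they were absent 2.38 times as often in nuclei without Uty, against at most 1.13 in the sets; in replicate 2 this ratio was 1.43, also above all of its sets (at most 1.31). A mixture of clusters with different Y levels would leave no excess within clusters, and the excess was 17.2% and 19.3% in clusters 16 and 20, above all sets, and 9.02% in cluster 15, the lowest, which lay inside the central range of its sets (percentile 96.7). Loss of the Y chromosome in part of the hepatocyte-like nuclei of this library may be a hypothesis for this pattern, from which shared silencing of the Y genes was not told apart, and no biological explanation was tested because the design names no group. Whether these nuclei are tumour cells was not tested either.

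Calls between Y-null and Y-detected nuclei were also made for matched autosomal sets. In macrophage-like nuclei, 1 of 3 classes with calls, the median set called at least as many genes as the Y genes. In endothelial-like and cholangiocyte-like nuclei the median set called fewer, and in all 3 classes the highest set called more. The calls for the Y genes can therefore not be told apart from a null call on any gene set of that level. In hepatocyte-like nuclei the fits differ in size, since the sets made 61 to 297 nuclei of replicate 3 null against 1894 for the Y genes, and 52 to 323 of replicate 1 against 50. The median and highest numbers called were 9 and 97 in hepatocyte-like, 1 and 7 in endothelial-like, 3.5 and 32 in macrophage-like, 0 and 10 in cholangiocyte-like and 0 and 14 in stellate/fibroblast-like nuclei. In dendritic-like nuclei they were 12 and 14 over 3 sets, against 0 for the Y genes, and the cholangiocyte-like values rest on 19 sets, of which 1 held 3 libraries. With 10 splits of the 6 sums, too few for a share under 0.05, the real split gave 2 genes against at most 1 in endothelial-like nuclei (1 of 10 as large), 0 against 47 in hepatocyte-like (10 of 10), 2 against 1 in macrophage-like (1 of 10) and 0 against 4 in stellate/fibroblast-like nuclei (10 of 10). Of the 10 splits, 4 part the pairs, the real one among them, and the rest of these 4 swap the states in 1 library. Such a split tests changes of opposite sign between libraries, so its count cannot weigh the real split. In hepatocyte-like nuclei these swapped splits called 9 to 47 genes against 0 for the real one. For Y genes called in either direction against hepatocyte-like nuclei, fitted for each class alone, the real split gave 1 gene in cholangiocyte-like, 1 in endothelial-like, 2 in stellate/fibroblast-like and 3 in dendritic-like nuclei (1 of 10 each) and 0 in macrophage-like, T/NK cell-like and B cell-like nuclei (10 of 10 each), against at most 0 in the others. Every other split of this kind puts sums of both classes in each group, so its low count cannot weigh the real split.

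The MUP-uPA transgene expresses urokinase, so Plau, its mouse gene, could be highest in hepatocyte-like nuclei. It was not: Plau stood at 1.91, 13.2 and 0.218 CPM in hepatocyte-like nuclei of replicates 1, 2 and 3 against 21.6, 27.8 and 10.3 in macrophage-like nuclei, and the highest ratio to the highest other class was 0.476. The counts therefore argue against a transgene transcript counted as Plau at a high level in these nuclei. A transgene that was little expressed and a transcript that was not counted as Plau were not told apart.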
